A study of Caenorhabditis elegans with 16 samples.

How the data were processed

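Small RNAs of young adult Caenorhabditis elegans hermaphrodites were extracted with the mirVana kit and cloned by a procedure that does not depend on a 5′ monophosphate, per the labels' protocols. Such cloning takes in secondary siRNAs made by RNA-dependent RNA polymerases, which carry a 5′ triphosphate. The 16 libraries covered 4 genetic backgrounds at 4 states of hrde-1, with 1 library for each combination and therefore no replicate of any genotype. Groups were taken from the sample titles, and each column of the series table was matched to a library by the name in its description. The labels carried 3 library-name prefixes: SG1116 for N2, SG0315 for hrde-1(tm1200), met-2 set-25 and met-2 set-25 hrde-1(tm1200), and SG0717 for the other 12 libraries. Another 27 library columns of the table matched no sample and were not used.

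The authors deposited 1 table of RPKM values per 1000 bp bin of the genome, with 100257 bins, and yes/no columns named GRH, GRTS and misanotated. What the per-million scaling counted is not stated. Bowtie 0.12.7 is named in the submitters' processing notes. The genome build, the treatment of reads with several matches, and the origin of the yes/no columns are not given in the sources used here. GRH marked 215 bins, GRTS 191, both of them 25, and misanotated 506. The abbreviations were not expanded, and as it is not stated on which libraries the authors set the marks, they are not independent evidence of any direction.

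Bins were named by the genes of the WBcel235 annotation (46890 genes) that overlap them, on either strand. Genes of the piRNA biotype were left out of the naming, so a bin said to overlap no named gene may hold piRNA genes. Coordinates are those of the deposited bins. The match of the bins to the annotation was checked in 100 windows along the genome, by correlating values with the annotation at shifts of up to 8 kb. In 96 windows the best match lay at shift 0 (median r over these 96 windows 0.39), and in 4 elsewhere, the last window of chromosome V lying 5 kb off. Gene names were withheld on chromosome V from 19 Mb onwards. The other 3 were the windows at 15 and 16 Mb of chromosome IV, best at −6 and −7 kb, and at 18 Mb of chromosome V, best at −8 kb, with r of −0.049, −0.055 and 0.046 at shift 0. At 17 Mb of chromosome V r was −0.054 at its best shift of 0. The check does not settle the match in these 4 windows, which hold ZK228.3, ZK228.4, ZK228.10, col-42, F59A1.9, fbxa-136, fbxa-192 and C38D9.2, and their names are less certain. Shorter stretches at the ends of chromosomes were not checked, among them that of chromosome IV from 17 Mb, which holds epic-1. Read strand and length are not separated in a bin, so siRNAs, fragments of the mRNA and other small RNAs over a gene add up, and reads of repeated copies, such as F07B7.1 with F07B7.2, the fbxa-192 bins, the T16G12 bins or the histone genes, cannot be assigned to 1 copy.

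Depth was read from the spacing of the lowest values. A single read was worth 1.451 to 6.3 RPKM per bin (median 2.45). The reads in the bins of a library, in units of 1000 reads, therefore numbered 143 to 500 (median 329.5). Of the low values, 49.4 to 77.4% (median 69.35) lay within 0.05 of a whole multiple of that step, too few to recover counts, and no count test was run. The RPKM values of a library summed to 67.7 to 96.7% of what a per-million scaling over all bins would give. In the shallowest library 3 reads were worth 18.9 RPKM and in the deepest 4.35 RPKM, and a bin listed at 0 may hold a low level.

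Values were analysed as log2(RPKM + 1) in the 25407 bins with a mean of at least 5 RPKM over the 16 libraries. Fold changes on this scale understate changes of low bins and depend on the pseudocount wherever 1 group lies near 0. limma 3.58.1 (lmFit, eBayes with a trend; R 4.3.3) was fitted, and bins with a Benjamini-Hochberg adjusted p under 0.05 in its two-sided test were called. The hrde-1 states were compared in pairs with the background as a block, and set-32 (both alleles) and met-2 set-25 were compared with the wild-type background with the state as a block. A set-32 by state contrast used all 16 libraries, its error coming from the difference between the set-32 alleles. As each genotype had 1 library, p-values measure the spread between backgrounds, states or alleles, not between cultures of a strain.

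Lists of loci were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The 19 lists were nuclear RNAi targets, ERGO-1 26G targets, sperm genes, oocyte and germline genes, RNAi factors, histone genes, microRNAs, the 21U-RNA clusters of chromosome IV, rRNA, tRNA, snRNA and snoRNA genes, markers of intestine, muscle, hypodermis and neurons, the mutated loci, GRH and GRTS. All but the last pair, which come from the deposited table, were written before the data were examined, as were the designs, the processing alternatives and the rule for named genes. Under that rule, called bins that changed the same way in all pairs and lay within 1 kb of each other formed a region. The 10 higher and 10 lower regions with the largest change of their best bin were named, with the genes over that bin. Nuclear RNAi targets and mutated loci were named whatever their values, and up to 4 members with the largest change from any other list. Where other genes are named, the text says that they were chosen after their values were seen.

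Bins called from the other 3 backgrounds, and changed at least 2 times, were followed in each background's own libraries as median log2 ratios to its never mutant library. They were set against 10000 random bin sets of equal size, matched over 20 strata of mean RPKM. Library shares of 13 classes and the summed RPKM of the mutated genes were compared with exact two-sided permutation tests. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for these.

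Alternatives were pseudocounts of 0.25 and 5, mean RPKM filters of 1 and 20 and no filter, centring on library medians, rescaling without microRNA, rRNA and tRNA bins, fits without the block or over all 16 libraries, leaving out each background, state or allele, and pairs of libraries with 1 prefix. Chosen after seeing the data were a comparison of set-32 with wild type in repaired libraries alone, the table-total class of a library (at least 85% of the per-million sum) as a term, leaving out the misanotated bins, the 1-prefix pairs for repaired against mutant libraries, and a simulation of overlaps between comparisons that share libraries.

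The fits were tested on simulated data of the same 25407 bins. For mutant against never mutant, 0, 31.3 and 48.5% of bins changed 2, 4 and 8 times were recovered, with 0 false among 53 calls. For set-32 against wild type the shares were 3, 38.8 and 63.6% (1 false of 71 calls), and for met-2 set-25 against wild type 0, 29.9 and 60.6% (0 false of 60). For the repaired libraries alone they were 0, 14.9 and 50% (1 false of 44). The interaction contrast recovered 0% at 2, 4 and 8 times. With larger changes, added afterwards, it recovered 7.5% at 8, 19.4% at 32 and 39.4% at 128 times, with 1 false of 45 calls. With no change simulated, 0 bins were called in 8 comparisons, which did not include the interaction contrasts or the repaired libraries alone. Simulated bins varied independently, with no difference by table-total class, so these runs do not test calls that follow that class.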

Results

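Small RNAs were profiled in 16 libraries of young adult C. elegans hermaphrodites, 1 for each combination of 4 genetic backgrounds and 4 states of hrde-1. HRDE-1 is a nuclear Argonaute protein of the germline that binds secondary siRNAs. The backgrounds were wild type, set-32(ok1457), set-32(red11) and the double mutant met-2(n4256) set-25(n5021). set-32 codes for a SET-domain protein, and met-2 and set-25 code for histone H3 methyltransferases. In each background hrde-1 had never been mutant, was mutant (tm1200), or had been repaired and grown for a few generations (F5, or F8 in set-32(ok1457)) or to F20. The series title names the question, the role of SET-32 in starting nuclear RNAi silencing across generations, and repair of hrde-1 lets the loci it acts on be followed from the mutant state onwards. Reads in the bins, in units of 1000, ranged from 143 in the met-2 set-25 F5 library to 500 in N2, with a median of 329.5. The 10 highest bins held 0.92 to 1.99% of a library.

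The table totals split the libraries in a way the design does not name. In 5 libraries, set-32(ok1457), set-32(red11), both set-32; hrde-1(tm1200) libraries and met-2 set-25 repaired F5, the summed RPKM reached 90.0 to 96.7% of a per-million sum, against 67.7 to 80.5% in the other 11. Intestine markers, the vitellogenin yolk protein genes vit-1 to vit-6 with elt-2 and ges-1, summed to 138 to 616 RPKM in those 5 libraries and to 4410 to 12400 RPKM in the other 11. Muscle markers such as unc-54 and unc-15 summed to 32 to 252 against 362 to 1610 RPKM, and hypodermis markers such as the cuticle collagen gene col-19 to 23.7 to 30.2 against 449 to 1240 RPKM. The medians of the other 11 libraries over those of the 5 were 47.3 for intestine, 10.2 for muscle and 25.3 for hypodermis, and 1.2 for sperm genes, 0.779 for oocyte and germline genes, 0.534 for neurons, 1.42 for rRNA, 0.73 for GRH and 0.852 for GRTS. Each mutant and its never mutant counterpart lay on one side of this split, whereas repaired set-32 libraries and their never mutant or mutant counterparts lay on opposite sides. The met-2 set-25 F5 library likewise lay across it from the never mutant, mutant and F20 libraries of its background.

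**Figure D1:**
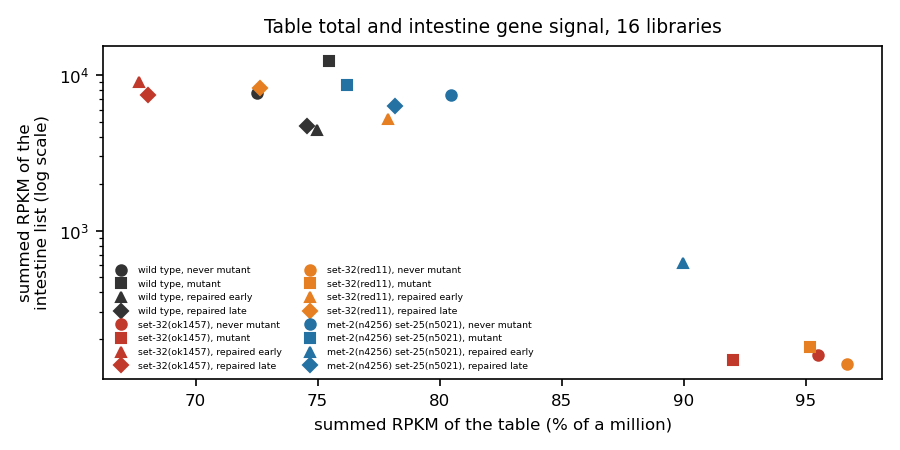
Summed RPKM over the intestine markers (log axis, y) against the table total as a percent of a per-million sum (x), 1 point for each of the 16 libraries. The 5 libraries with totals of 90.0 to 96.7% lie at 138 to 616 RPKM and the other 11 at 4410 to 12400 RPKM.

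The mutated genes were examined first, as summed RPKM over each gene in the libraries that carry the mutation and in the other 12 libraries. Small RNAs over met-2 were at a mean of 63.8 RPKM (n = 4; range 52.1 to 77.4) in met-2 set-25 libraries and at 237 ± 73.7 RPKM (151 to 390, n = 12) in the others (exact permutation p = 0.000549, the smallest possible, adjusted over 5 tests 0.00275). set-25 was at 68.0 ± 5.82 against 137 ± 39.7 RPKM (exact permutation p = 0.0011, adjusted 0.00275; range 60.4 to 74.6 against 71.0 to 193). Over hrde-1 itself the tm1200 libraries had 309 ± 69.4 RPKM (n = 4; 248 to 390) and the others 462 ± 121 (280 to 711; exact permutation p = 0.0187, adjusted 0.0312). set-32 passed in neither allele, with 49.1 ± 10.5 against 58.9 ± 17.3 RPKM for ok1457 (exact permutation p = 0.334, adjusted 0.418) and 58.5 ± 20.3 against 55.7 ± 15.5 RPKM for red11 (exact permutation p = 0.83, adjusted 0.83). The 12 libraries set against each allele included those of the other set-32 allele. The hrde-1 sums were at 326 RPKM in N2, 248 in the mutant, 438 at F5 and 424 at F20 in wild type, and at 466, 253, 592 and 453 in met-2 set-25. In set-32(ok1457) they were at 589, 390, 389 and 280, and in set-32(red11) at 711, 343, 491 and 385. Repaired ok1457 libraries lay at or below their mutant, so these sums do not check their labels, and the set-32 sums do not check those of set-32.

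Loss of hrde-1 changed small RNAs at 289 bins across the 4 backgrounds, 108 higher in 63 regions and 181 lower in 108 regions. Over ZK228.3 (V:18458001–18459000, where the match of bins to names was weak) the mutants had 160 ± 88.2 RPKM (SD, n = 4) and the never mutant libraries were all listed at 0 (adjusted p = 0.00677). asm-3, an acid sphingomyelinase gene (IV:520001–521000), had 112.7 ± 57.2 against 0.86 ± 1.22 RPKM, a log2 change of 5.93 ± 0.49 (SE, adjusted p = 0.00677). xdh-1, which codes for xanthine dehydrogenase (IV:14409001–14410000), stood at 74.1 ± 22.5 against 1.22 ± 1.41 RPKM (log2 5.27 ± 0.44, adjusted p = 0.00677). Also among the 10 most raised regions were T11F9.19 (6.13 ± 0.71), ZK228.4 (5.61 ± 0.56), the ground-like gene grl-18 (5.12 ± 0.59), Y47A7.2 (5.08 ± 0.73), Y61A9LA.7 (5.0 ± 0.48), Y53H1B.2 (4.94 ± 0.60) and a bin of C42D4.19 and the chemoreceptor gene str-1 (4.83 ± 0.54), with adjusted p from 0.0081 to 0.0176. Never mutant means were 6.47 ± 8.22 RPKM over Y47A7.2, 2.79 over T11F9.19 (8.7 in N2) and lower over the others, so the sizes depend on the pseudocount.

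The lowered regions were led by Y38F2AL.12 (IV:2318001–2319000), at 11.5 ± 18.1 RPKM in mutants and 166 ± 53.4 in never mutant libraries (log2 −4.90 ± 0.61, adjusted p = 0.0131). The mechanosensory channel gene trp-4 fell from 49.2 ± 18.5 to 6.46 ± 12.7 RPKM (−4.28 ± 0.71, adjusted p = 0.0281). eri-6, a helicase gene of the ERGO-1 siRNA pathway, fell from 98.5 ± 62.4 to 7.30 ± 10.7 RPKM (−4.08 ± 0.69, adjusted p = 0.0316), and the bin it shares with sosi-1 had a log2 change of −4.03 ± 0.42. C18H2.9 (275 ± 130 to 40.8 ± 58.6 RPKM), T16G12.12 with T16G12.10 (207 ± 155 to 18.6 ± 18.8) and Y54G2A.12 (75.6 ± 44.2 to 5.04 ± 5.59) followed, with log2 changes of −3.62 ± 0.48, −3.86 ± 0.48 and −3.97 ± 0.41. The other regions were Y69A2AL.2 (−3.95 ± 0.62), T28D6.4 (−3.93 ± 0.74), Y38F2AR.12 (−3.58 ± 0.58) and II:11259001–11260000, which overlaps no named gene (−3.65 ± 0.57). Among the 289 bins, 7 were marked misanotated, 6 of them lower.

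Of the nuclear RNAi targets, 6 of 22 tested bins fell and 0 rose, or 9 lower and 3 higher adjusted over the list alone. These 6 were F15D4.5 (log2 −2.11 ± 0.27 at II:13246001–13247000 and −1.13 ± 0.19 next to it), C38D9.2 (−2.41 ± 0.31 and −1.73 ± 0.31), a bin of F07B7.1 and F07B7.2 (−2.02 ± 0.24) and R03D7.2 (−1.72 ± 0.25). F15D4.5 was lower in every background: 694 to 90.7 RPKM in wild type, 1230 to 526 in set-32(ok1457) and 964 to 184 in set-32(red11), and summed over the gene 969 to 478 in met-2 set-25. Other bins of R03D7.2 had higher values without passing the threshold (2.95 ± 0.65, adjusted p = 0.0837; 2.30 ± 0.58, adjusted p = 0.131). Summed over each gene, the mean log2 differences over the 4 backgrounds were −1.30 for C38D9.2 (SD 0.25), −1.27 for F15D4.5 (0.33), −1.06 for F07B7.2 (0.83), −0.50 for bath-45 (0.16), −0.34 for W05H12.2 (0.39) and 0.20 for R03D7.2 (1.16). The list had a median of −0.61 (camera adjusted p = 0.00021), and adjusted p = 0.39 with an estimated correlation.

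Bins the authors marked GRH fell in 38 of 191 cases and rose in 4, or 94 and 11 adjusted over the list alone, with a median of −0.78 (camera adjusted p = 2.1e-23; adjusted p = 0.17 with an estimated correlation). The 4 that rose, named after their values were seen, were Y23H5A.8 (2.22 ± 0.33), F55A3.7 (2.28 ± 0.30), Y47H9C.9 (2.69 ± 0.36) and a bin of C34C12.2 and C34C12.1 (3.67 ± 0.53). GRTS bins went both ways, 22 of 181 lower and 13 higher (65 and 32 adjusted over the list alone), the raised ones led by ZK228.10 (6.21 ± 0.79), grl-18, Y47A7.2 and W03G1.2 (4.71 ± 0.65). Their median was −0.51 and their mean −0.10 (camera adjusted p = 1.3e-05; adjusted p = 0.59 with an estimated correlation). If calls and marks were independent, 1.36 GRH and 1.29 GRTS bins would be expected among the 181 lower bins. The origin of both marks is not stated, so these counts are not independent evidence of a direction.

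Histone genes rose in 4 of 73 tested bins, all over his-51 or his-52 (1.97 ± 0.34 to 2.0 ± 0.33), or 16 adjusted over the list alone. Their median was 0.38 (camera adjusted p = 3e-09; adjusted p = 0.75 with an estimated correlation), and reads of the near-identical histone copies cannot be told apart. Oocyte and germline genes had 0 called bins of 73, also 0 adjusted over the list alone, and a median of 0.26 (camera adjusted p = 0.0042; adjusted p = 0.35 with an estimated correlation). The 21U-RNA clusters had 6 bins higher and 8 lower of 2640 (4 and 4 adjusted over the list alone; median 0.13, camera adjusted p = 0.29), and snoRNA genes 1 higher of 220 (1 adjusted over the list alone), T07D4.7 at 2.49 ± 0.40 (median 0.04, camera adjusted p = 0.84). No bin passed in the remaining lists. ERGO-1 26G targets had a median of 0.01 (camera adjusted p = 0.43) with 2 bins of fbxb-97 lower adjusted over the list alone (−1.09 ± 0.26 and −0.88 ± 0.21). Medians and camera adjusted p were 0.30 and 0.066 for sperm genes, 0.13 and 0.16 for intestine, −0.25 and 0.29 for muscle, −0.21 and 0.41 for neurons, −0.04 and 0.84 for hypodermis, and 0.09 and 0.61 for RNAi factors. For microRNAs they were 0.03 and 0.89, for rRNA 0.13 and 0.19, for tRNA −0.02 and 0.43, for snRNA 0.09 and 0.29 and for the mutated loci −0.05 and 0.43.

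How many bins passed depended on which backgrounds entered. Without set-32(red11) limma called 0 bins, without met-2 set-25 17 higher and 25 lower, and without set-32(ok1457) 52 higher and 85 lower. Without the wild-type pair, the only one whose libraries carried different name prefixes, it called 107 higher and 163 lower. With no filter on low bins 0 were called, and with a pseudocount of 0.25 37 higher and 78 lower.

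Repaired libraries had fewer small RNAs than hrde-1 mutants at a small number of bins. In early repaired libraries 11 bins in 8 regions were lower than in the mutants and 0 were higher, and in F20 libraries 33 bins in 21 regions were lower and 1 was higher. With a pseudocount of 0.25 limma called 0 bins at both times, and other splits of these libraries, made without regard to the block, gave up to 12 bins early and 125 at F20. T11F9.19 (V:11492001–11493000) went from 203 ± 132 RPKM in mutants to 0.51 ± 1.01 in early repaired libraries (log2 −7.0 ± 0.49, adjusted p = 0.00378) and was lower at F20 as well (−6.42 ± 0.56, adjusted p = 0.0194). W03G1.2 fell by 5.43 ± 0.65 on the log2 scale early and by 4.74 ± 0.66 at F20, C44B12.6 by 4.95 ± 0.58 and 4.94 ± 0.63, and F57A8.1 early from 72.9 ± 19.9 to 3.65 ± 2.78 RPKM (−4.28 ± 0.48, adjusted p = 0.0455). The other early regions overlapped no named gene: IV:6007001–6008000 (−6.08 ± 0.76), which lies in a 21U-RNA cluster, V:10868001–10869000 (−5.58 ± 0.63), I:11448001–11449000 (−3.75 ± 0.46) and IV:918001–919000 (−3.58 ± 0.37). At F20 ZK228.10 stood at 0.66 ± 1.19 against 252 ± 135 RPKM (−7.18 ± 0.70), Y43F4A.1 at 1.34 ± 1.24 against 153 ± 117 (−5.63 ± 0.74), ZK228.4 at 2.6 ± 2.17 against 184 ± 131 (−5.49 ± 0.77) and asm-3 at 3.61 ± 3.18 against 112.7 ± 57.2 (−4.77 ± 0.67, adjusted p = 0.0452). Unnamed regions at V:10869001–10870000 and IV:1450001–1451000 had −5.60 ± 0.73 and −5.06 ± 0.61. The bin that rose, I:11072001–11073000, overlaps no named gene and went from 9.03 ± 6.70 to 63.2 ± 36.9 RPKM (2.92 ± 0.41, adjusted p = 0.0478).

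Of the bins lower after repair, 9 of 11 early and 22 of 33 at F20 were among the 108 that were higher in mutants. Both comparisons use the same mutant libraries. In 20 simulations of all libraries without any change, the overlaps had means of 1.1 bins (0 to 4) and 3.75 bins (2 to 7), and independent lists would share 0.05 and 0.14. With the mutant libraries split between the comparisons, 2 backgrounds in each, the overlaps were 4 to 10 (median 5) and 11 to 21 (median 15) over 6 splits. Simulated and split overlaps took the bins of lowest p in each direction, as many as in the real lists, called or not. The medians of all tested bins were −0.21 in both comparisons, and with log2 values centred on each library's median 1 bin was lower early and 15 were lower at F20. limma called 0 bins early without set-32(red11), 1 lower without met-2 set-25, and 2 higher and 6 lower without set-32(ok1457). At F20 it called 0 without either set-32(red11) or met-2 set-25, and 3 higher and 3 lower without set-32(ok1457). Pairs that share a library-name prefix, which are the set-32 pairs and lie across the split of table totals, gave 63 higher and 61 lower bins early and 198 higher and 278 lower at F20. With the table-total class as a term, added after seeing the data, limma called 16 higher and 76 lower early and 6 and 11 at F20.

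GRTS bins were lower in 3 of 181 cases early and in 7 at F20, and 0 were higher (17 lower and 5 higher, then 28 lower and 18 higher, adjusted over the list alone). Their medians, 0.23 and 0.24, and means, −0.09 at both times, differ in sign, while camera placed the list above the other bins (adjusted p = 0.0028 and 0.0012; adjusted p = 0.95 and 0.59 with an estimated correlation). GRH bins had 0 calls at both times, with 5 higher and 5 lower, then 18 higher and 10 lower, adjusted over the list alone. The GRH medians of 0.25 and 0.26 lay above the median of all bins (camera adjusted p = 1.7e-06 and 3e-08; adjusted p = 0.95 and 0.62 with an estimated correlation). Nuclear RNAi targets had 0 called bins and medians of 0.00 and 0.01 (camera adjusted p = 0.86 and 0.99), with 1 bin lower early, and 1 higher and 2 lower at F20, adjusted over the list alone. Intestine markers had medians of 1.36 early and 2.39 at F20 (camera adjusted p = 7e-08 and 2.5e-19; adjusted p = 0.95 and 0.59 with an estimated correlation) and muscle markers 0.34 and 1.19 (camera adjusted p = 0.027 and 2.2e-06; adjusted p = 0.95 and 0.62 with an estimated correlation). Hypodermis markers had 1.73 at F20 (camera adjusted p = 0.0004; adjusted p = 0.59 with an estimated correlation). These tissue lists follow the 5 libraries with high table totals, which include both set-32 mutants. Histone, snRNA and snoRNA genes had medians of −0.46, −0.45 and −0.42 at F20 (camera adjusted p = 0.00016, 1.9e-07 and 9.1e-06; adjusted p = 0.74, 0.59 and 0.59 with an estimated correlation).

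Between F20 and early repaired libraries limma called 0 bins, and 435 higher and 528 lower had an unadjusted p under 0.05. GRH and nuclear RNAi targets had medians of 0.03 and −0.01 (camera adjusted p = 0.26 and 0.95). Intestine and hypodermis markers had medians of 0.94 and 1.04 (camera adjusted p = 1.3e-15 and 0.0014; adjusted p = 0.84 for both with an estimated correlation), and the met-2 set-25 F5 library is among the 5 with high table totals.

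No single bin set repaired libraries apart from never mutant ones across the 4 backgrounds. limma called 0 bins for early repaired libraries (205 higher and 702 lower at an unadjusted p under 0.05) and 0 at F20 (271 and 807). As groups, GRH bins had pooled medians of −0.48 early and −0.39 at F20, beyond the −0.17 of all bins (camera adjusted p = 1.2e-06 and 1.3e-05; adjusted p = 0.94 and 0.80 with an estimated correlation). By background, the GRH medians were 0.06 and 0.04 in wild type and 0.21 and 0.05 in met-2 set-25, early and at F20. They were −0.66 and −0.44 in set-32(red11) and −1.12 early in set-32(ok1457), whose pairs cross the split of table totals. The early pair of met-2 set-25 crosses it as well. Relative to random sets, wild type was at −0.25 and −0.26 and met-2 set-25 at −0.04 and 0.01. On that scale red11 was at −0.38 and −0.07 and ok1457 at −0.63 and −0.50. Nuclear RNAi targets had pooled medians of −0.63 and −0.76 (camera adjusted p = 0.00019 and 0.00012; adjusted p = 0.94 and 0.74 with an estimated correlation), with 4 bins lower and 1 higher at each time adjusted over the list alone. Among those were C38D9.2 at V:17571001–17572000 (−2.17 ± 0.60 early, −1.99 ± 0.55 at F20) and V:17568001–17569000 (2.37 ± 0.71 and 2.30 ± 0.66) and F07B7.2 (−2.18 ± 0.53 and −2.15 ± 0.66). Intestine markers were at 1.60 and 2.54 (camera adjusted p = 1.4e-14 and 2.9e-36; adjusted p = 0.94 and 0.74 with an estimated correlation), and the set-32 pairs lie across the split of table totals. Those set-32 pairs alone, the only ones that share a library-name prefix, gave 652 called bins early and 410 at F20.

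At hrde-1-dependent loci, the median after repair was close to the N2 level in wild type, though below that of random sets, and lay below the never mutant level in set-32(ok1457). With 1 library per genotype and generation these ratios describe the libraries and were not tested. In wild type, 163 bins lowered by hrde-1 loss in the other 3 backgrounds had a median log2 ratio to N2 of −1.60 in the mutant, and of 0.01 at both F5 and F20. The medians of matched random sets were 0.28, 0.31 and 0.30, and 4 and 3 of 10000 random sets were as low at F5 and F20. In set-32(ok1457), 85 such bins had medians of −1.62 in the mutant, −2.95 at F8 and −2.67 at F20 (random sets 0.03, −0.49 and −0.50), below all 10000 random sets at each state. In met-2 set-25, 25 bins had −1.74, −0.04 and 0.04, with 794 and 5352 of 10000 random sets as low at F5 and F20. For set-32(red11) no bin was called from the other 3 backgrounds. Bins raised by hrde-1 loss had medians of 1.69, −0.37 and −0.09 in wild type (105 bins), 3.25, 1.17 and 0.76 in set-32(ok1457) (52 bins) and 3.99, −0.13 and 0.08 in met-2 set-25 (17 bins).

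With the 181 lower bins called from all 4 backgrounds, red11 could be followed too, although the never mutant and mutant libraries then served to choose the bins, which can shift every ratio to the never mutant library. In wild type the change of bins moved F5 from −0.30 to −0.50 and F20 from −0.29 to −0.46 relative to random sets, and no value without an effect was computed for it. Relative to random sets, set-32(red11) was at −2.64 in the mutant, −1.55 at F5 and −0.61 at F20. With a pseudocount of 5, 30 lower bins were called without red11 and had −2.81, −2.29 and −1.16 there. set-32(ok1457) was at −1.76, −2.15 and −1.84, wild type at −2.58 in the mutant, and met-2 set-25 at −2.16, −0.17 and −0.02. The 108 raised bins were at 3.92, 1.93 and 1.71 in red11 and at 2.83, 1.42 and 0.98 in ok1457. They were at 2.46, −0.26 and 0.06 in wild type and at 3.46, −0.02 and 0.15 in met-2 set-25. The never mutant set-32 libraries have high table totals and their repaired libraries do not, so these ratios cross that split. The met-2 set-25 ratio at F5 crosses it too, as that library has a high total and its never mutant library does not.

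**Figure D2:**
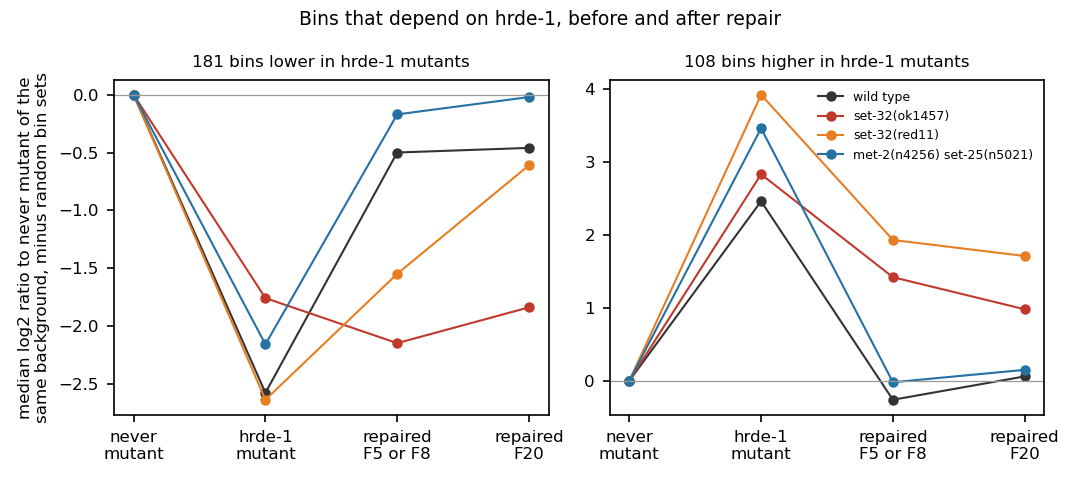
Median log2 ratio to the never mutant library of the same background, minus the median of matched random bin sets (y), by hrde-1 state (x) for the 181 bins lower and the 108 bins higher in hrde-1 mutants, 1 line for each of the 4 backgrounds. At F20 the lower bins stand at −0.46 in wild type, −0.02 in met-2 set-25, −0.61 in set-32(red11) and −1.84 in set-32(ok1457).

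Bins of F15D4.5 differed in this. At II:13246001–13247000, a GRH bin, small RNAs in wild type were at 694 RPKM before, 90.7 in the hrde-1 mutant, 513 at F5 and 586 at F20, and in met-2 set-25 at 483 before, 538 at F5 and 723 at F20. In set-32(ok1457) they were at 1230, 526, 57.4 and 49, and in set-32(red11) at 964, 184, 89.8 and 57.2. In the next bin, II:13245001–13246000, wild type had 123, 144, 34.8 and 38.3 RPKM, ok1457 127, 134, 106 and 185, and red11 144, 166, 114 and 135. Summed over the gene, F15D4.5 had 1310 RPKM at F20 in wild type, 1340 in met-2 set-25, 432 in ok1457 and 481 in red11, from 1360, 969, 2560 and 1950 before. bath-45 had 1410, 1040, 1010 and 1080 RPKM at F20, from 1260, 949, 1730 and 1260.

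**Figure D3:**
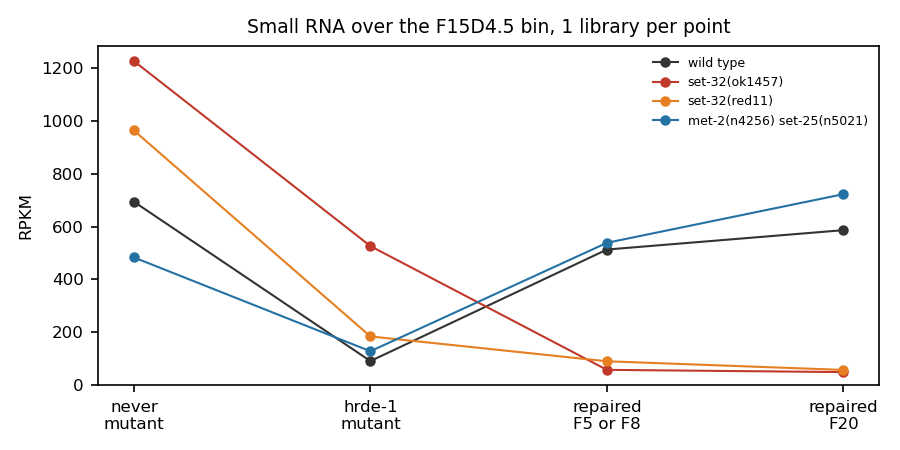
RPKM of the F15D4.5 bin at II:13246001–13247000 (y) by hrde-1 state (x), 1 point for each of the 16 libraries and 1 line for each background. At F20 wild type and met-2 set-25 stand at 586 and 723 RPKM and the set-32 libraries at 49 and 57.2 RPKM.

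Over all hrde-1 states, 8 set-32 libraries and 4 wild-type ones differed in 0 bins by limma, with 2230 higher and 754 lower at an unadjusted p under 0.05. The smallest adjusted p was 0.052, and the median of all bins was 0.17. Intestine markers had the largest shift, a median of −2.54 with 0 called bins and 28 lower adjusted over the list alone, led by vit-1 (−3.04 ± 1.01), vit-2 (−2.99 ± 0.99) and vit-6 (−2.95 ± 0.97; camera adjusted p = 2.7e-27; adjusted p = 0.47 with an estimated correlation). Hypodermis markers had −2.35 with 7 lower adjusted over the list alone (col-19 −3.20 ± 1.15, camera adjusted p = 1.4e-06), and muscle markers −1.80 (unc-54 −2.77 ± 0.90, camera adjusted p = 2.5e-11), both with adjusted p = 0.47 with an estimated correlation. Of the 8 set-32 libraries 4 are among those with high table totals and low tissue signal, and 0 of the wild-type ones. Over vit-2 (X:5101001–5102000), set-32(ok1457) had 0 RPKM never mutant, 8.52 mutant, 359 at F8 and 315 at F20, while wild type had 302, 433, 150 and 155. Nuclear RNAi targets had a median of 0.25 (camera adjusted p = 0.59). GRH bins had −0.11 (camera adjusted p = 9.2e-05; adjusted p = 0.78 with an estimated correlation). Leaving out the never mutant libraries gave 12 higher and 2 lower bins, and leaving out the mutants 2 and 2. With the table-total class as a term, added after seeing the data, limma called 58 higher and 46 lower.

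A comparison within the repaired libraries, chosen after seeing the data, set 4 set-32 libraries against 2 wild-type ones that share a prefix and have table totals of 67.7 to 77.9%. The wild-type libraries were 2 generations of 1 repaired genotype, and the set-32 ones 2 generations of each allele. The fit and the SDs took generations as separate samples, so a level particular to repaired wild type would be called too. It called 42 bins higher in 34 regions and 30 lower in 23 regions. R11E3.18 (IV:4769001–4770000) had 93.7 ± 47 RPKM in set-32 (SD, n = 4) and 0.08 ± 0.11 in wild type (n = 2; limma log2 6.22 ± 0.58, adjusted p = 0.0225). The F-box gene fbxa-136 had 40.4 ± 9.56 RPKM (5.33 ± 0.45), Y61A9LA.7 80.6 ± 24.8 against 1.47 ± 1.82 (5.23 ± 0.49), Y16B4A.2 111 ± 24.5 against 5.66 ± 0.96 (4.05 ± 0.31) and the TRPV channel gene osm-9 81.8 ± 40.6 against 3.93 ± 1.59 (3.96 ± 0.53). C34F6.7 with idh-2 (5.05 ± 0.67) and casc-3 with the guanylate cyclase gene gcy-35 (4.36 ± 0.53) were also higher. These are differences from wild type, not changes over repair. Over C34F6.7 with idh-2, wild type went from 30.5 RPKM in N2 to 0.1 in both repaired libraries. There ok1457 went from 71.5 to 15.6 and 29.8, and red11 from 117 to 81.2 and 41.2. Over Y16B4A.2 wild type went from 53.7 to 6.34 and 4.98, ok1457 from 92.8 to 112 and 144, and red11 from 74.5 to 102 and 85.8. T04A8.13 (38.4 ± 18.6 RPKM), C11G10.1 (16.8 ± 3.09) and V:7980001–7981000 (21 ± 7.81) were listed at 0 in both wild-type libraries. Repaired met-2 set-25 libraries, which were not in this fit, lay with set-32 at some of these bins and nearer wild type at others. At F5 and F20 they had 37.8 and 28.5 RPKM over T04A8.13 and 50.4 and 36.1 over C34F6.7 with idh-2, so these differences were not particular to set-32. They had 0.07 and 4.54 over fbxa-136 and 0.46 and 2.08 over Y61A9LA.7.

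Among the lower regions, B0001.5 (IV:12142001–12143000) had 9.40 ± 3.26 RPKM in repaired set-32 and 162 ± 4.83 in wild type (−4.02 ± 0.35, adjusted p = 0.0191). F15D4.5 was lower by 3.13 ± 0.27 on the log2 scale (adjusted p = 0.0191), and the F-box genes fbxa-192 (11 ± 4.90 against 166 RPKM) and fbxa-216 (1.85 ± 1.55 against 83.6 ± 16.4) by 3.90 ± 0.47 and 5.09 ± 0.72. trp-4 had 0.84 ± 1.61 against 64.7 ± 1.75 RPKM (−5.48 ± 0.78), D2045.9 1.08 ± 1.25 against 99.5 ± 23.3 (−5.80 ± 0.75), and the kinase gene dlk-1 11.7 ± 5.24 against 105 ± 23.9 (−3.18 ± 0.45). saeg-1 (−5.74 ± 0.76) and a fbxa-192 copy at V:17642001–17643000 (−3.50 ± 0.41) were lower too. The neuropeptide receptor gene pdfr-1 was listed at 0 in the 4 set-32 libraries at III:6638001–6639000 and at 67.9 ± 49.1 RPKM in wild type. Copies of fbxa-192 and of F07B7.1 with F07B7.2 may share reads. Repaired met-2 set-25 libraries were low as well at some of these bins. At F5 and F20 they had 0 and 7.02 RPKM over trp-4 and 0 and 3.55 over pdfr-1 at III:6638001–6639000. At others they were not low, with 220 and 206 RPKM over B0001.5 and 120 and 90.4 over fbxa-216.

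GRH bins were lower than in wild type in 5 of 191 cases in this comparison and higher in 0 (39 lower and 4 higher adjusted over the list alone): B0001.5, F15D4.5, F15D4.6, T05E8.1 and K01A11.3, the last 3 named after their values were seen (−2.52 ± 0.33, −1.78 ± 0.21 and −2.13 ± 0.30). Their list median was −0.53 (camera adjusted p = 4.6e-15; adjusted p = 0.48 with an estimated correlation). ERGO-1 26G targets had 0 called bins, also 0 adjusted over the list alone, and a median of −0.46 (camera adjusted p = 0.00049; adjusted p = 0.48 with an estimated correlation). Nuclear RNAi targets went both ways, 2 bins higher and 2 lower (3 and 6 adjusted over the list alone; median −0.43, camera adjusted p = 0.13). C38D9.2 at V:17568001–17569000 was higher than in wild type by a log2 of 2.88 ± 0.23 and F15D4.5 at II:13245001–13246000 by 1.82 ± 0.25, while F15D4.5 at II:13246001–13247000 and F07B7.2 (−2.58 ± 0.30) were lower. Intestine, muscle and hypodermis markers had medians of 0.63, 0.83 and 0.48 with 0 called bins (camera adjusted p = 7.8e-18, 2.9e-05 and 0.0076; adjusted p = 0.48 for each with an estimated correlation), in libraries on one side of the split of table totals. With a mean filter of 1 RPKM, or no filter, limma called 0 bins, with a pseudocount of 0.25 21 higher and 12 lower, and with ok1457 alone 1271.

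At the 181 bins lower in hrde-1 mutants, repaired set-32 libraries lay below the wild-type library of the same class. Median log2 ratios relative to random sets were −1.63 for ok1457 F8, −1.51 for ok1457 F20, −1.23 for red11 F5 and −0.67 for red11 F20, with 165, 162, 150 and 125 of the 181 bins below 0. met-2 set-25 was at −0.55 and −0.49, and in all 6 comparisons 0 of 10000 random sets were as low. Its early library, unlike the wild-type one, has a high table total, so that ratio crosses the split. At the 108 bins higher in mutants the set-32 libraries, in that order, were at 0.95, 0.47, 0.75 and 0.32 and met-2 set-25 at −0.92 and −0.87. At GRTS bins set-32 was between −0.12 and 0.01 and met-2 set-25 at −0.46 and −0.49. At the 126 bins outside GRH and GRTS, the set-32 values relative to random sets were −1.47, −1.05, −1.10 and −0.64.

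The contrast of early repaired against never mutant between set-32 and wild type called 86 bins, 66 higher in 47 regions and 20 lower in 17. The higher ones were led by cuticle collagens: col-129 (9.56 ± 1.31, SE), col-139 (9.44 ± 1.19), col-42 (8.65 ± 0.96), col-19 (8.38 ± 1.29), a bin of col-159 and col-160 (8.21 ± 0.97) and col-184 (7.77 ± 0.86), called at adjusted p of 0.0246 to 0.0448 by limma. With them were the yolk protein gene vit-2 (8.10 ± 1.01, adjusted p = 0.0249), the calsequestrin gene csq-1 (8.69 ± 1.36), epic-1 (8.72 ± 1.42, where the match of bins to names was not checked) and the cathepsin gene cpl-1 (7.91 ± 1.23). Intestine markers had 18 of 36 bins higher (34 adjusted over the list alone), hypodermis markers 4 of 8 (7 higher and 1 lower) and muscle markers 3 of 21 (18 higher), with medians of 5.93, 6.50 and 5.08. Camera gave adjusted p = 6.5e-58, 1.2e-12 and 1.6e-23, and adjusted p = 0.032, 0.032 and 0.051 with an estimated correlation. The never mutant set-32 libraries are among the 5 with high table totals and low values of these same genes, so that the contrast and that split coincide. Over col-19 (X:422001–423000), set-32(ok1457) went from 0 to 189 RPKM and red11 from 2.45 to 99.9, whereas wild type went from 301 to 66.7.

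The lower bins of this contrast included Y47G6A.5 (−7.93 ± 1.03), ZK673.4 (−7.78 ± 1.07), Y51H7C.42 (−7.43 ± 1.19), F59A1.9 (−7.41 ± 0.69), the synaptic gene unc-10 (−7.35 ± 0.89), the demethylase family gene jmjd-3.2 (−6.86 ± 0.92), Y9D1A.1 (−6.75 ± 1.02), a bin of cox-6B and pho-9 (−6.41 ± 0.90), T03D3.5 (−6.20 ± 0.91) and btb-11 (−5.93 ± 0.81). N2, the only library of its name prefix, was the lowest of the 4 wild-type libraries at 19 of the 20 lower bins. Y47G6A.5 had 0 RPKM in N2 against 15.1 in the mutant, 80 at F5 and 61.1 at F20, and unc-10 had 0 against 56.1, 58 and 51.4, so that these values rest on N2. N2 was the highest of the 4 at 42 of the 66 higher bins. F59A1.9 went from 360 to 21.1 RPKM in ok1457 and from 247 to 31.4 in red11, and from 10.2 to 169 in wild type. Nuclear RNAi targets had 1 bin higher, C38D9.2 (4.63 ± 0.56), and 0 lower (1 and 3 adjusted over the list alone; median −0.95, camera adjusted p = 0.24), and F15D4.5 had −3.47 ± 0.81 (adjusted p = 0.107). GRH bins had 0 calls, also 0 adjusted over the list alone, and a median of −0.89, against −0.65 for all bins (camera adjusted p = 0.0002; adjusted p = 0.52 with an estimated correlation). ERGO-1 26G targets had −1.37 with 4 bins lower adjusted over the list alone, E01G4.5 at −6.01 ± 1.04 among them (camera adjusted p = 0.00045; adjusted p = 0.41 with an estimated correlation). Centred on library medians the contrast gave 130 higher and 20 lower bins, with a pseudocount of 0.25 31 and 11, with a filter at 1 RPKM 0 and 0, at 20 RPKM 112 and 129, and with no filter 2943 and 1805. Without either set-32 allele, with the spread from an additive fit, it gave 0.

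The matching contrast for the hrde-1 mutation itself, whose pairs do not cross the split of table totals, called 0 bins by limma, with 691 higher and 1371 lower at an unadjusted p under 0.05 and a median of −0.37. With no filter it called 2505 higher and 2044 lower. Sperm genes had a median of 1.72 (camera adjusted p = 2.5e-13; adjusted p = 0.63 with an estimated correlation) and nuclear RNAi targets 0.35 (camera adjusted p = 0.0074; adjusted p = 0.47 with an estimated correlation).

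In met-2 set-25 animals 37 bins were higher than in wild type over the 4 hrde-1 states, in 26 regions, and 36 were lower, in 26 regions. Y110A2AL.1 (II:2876001–2877000) had 192 ± 86.8 against 1.52 ± 1.09 RPKM (log2 6.31 ± 0.51, adjusted p = 0.0128) and the collagen gene col-87 108 ± 95.1 against 0.23 ± 0.17 (6.10 ± 0.59, adjusted p = 0.0175). seld-1, which codes for selenophosphate synthetase, had 256 ± 37.4 against 16.4 ± 19.9 RPKM (4.49 ± 0.53, adjusted p = 0.0191). C55C3.7 (4.97 ± 0.52), T23F4.2 (4.96 ± 0.55), plep-1 (4.78 ± 0.65), the folate transporter gene folt-1 (4.71 ± 0.70), V:9687001–9688000, which overlaps no named gene (4.52), K10D3.4 (4.34 ± 0.64) and trpp-5 (4.25 ± 0.48) made up the rest. The lower regions were led by Y16E11A.4 (2.36 ± 4.68 against 105 ± 31.6 RPKM, −5.82 ± 0.69), Y54G2A.20 (1.94 ± 1.45 against 80.3 ± 30.7, −4.89 ± 0.53) and the serotonin receptor gene ser-5 (−4.86 ± 0.55). R03D7.3 (−4.66 ± 0.65), E02H9.1 (−4.42 ± 0.66), eri-6 (−4.40 ± 0.62), the nuclear receptor gene nhr-236 (−4.39 ± 0.63), H04D03.7 (−4.25 ± 0.59), F52C6.14 (−4.21 ± 0.57) and Y54G2A.21 (−4.12 ± 0.60) followed.

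GRH bins fell in 4 of 191 cases in met-2 set-25 and rose in 0 (20 lower and 1 higher adjusted over the list alone), at eri-6 (2 bins), Y71A12B.13 (−2.90 ± 0.43) and T16G12.12 with T16G12.10 (−3.39 ± 0.46). The T16G12 bin held 27.9, 0, 6.3 and 24.6 RPKM in the met-2 set-25 libraries and between 23.7 and 154 in wild type. The GRH median was −0.27 and the GRTS median −0.56, against 0.11 for all bins, with 1 GRTS bin lower, that of R03D7.3 (35 adjusted over the list alone). Camera gave adjusted p = 2.5e-11 and 2.5e-24, and adjusted p = 0.35 for both with an estimated correlation. Nuclear RNAi targets rose in 1 bin, R03D7.2 (2.75 ± 0.41), and fell in 0 (2 and 3 adjusted over the list alone; median −0.17, camera adjusted p = 0.019; adjusted p = 0.61 with an estimated correlation). Of the mutated loci 1 bin fell, over met-2 itself (−3.49 ± 0.54), or 6 adjusted over the list alone (median −0.83, camera adjusted p = 2e-05; adjusted p = 0.45 with an estimated correlation). The 21U-RNA clusters had 5 bins higher and 2 lower, the same counts adjusted over the list alone, with seld-1 and C55C3.7 among the genes in them (camera adjusted p = 0.34). Intestine and hypodermis markers had medians of −0.72 and −1.14 (camera adjusted p = 1.5e-08 and 0.00069; adjusted p = 0.76 for both with an estimated correlation), and the met-2 set-25 F5 library is among the 5 with high table totals. Centring on library medians gave 54 higher and 82 lower bins. Without the F20 libraries limma called 0, without the early ones 1 higher and 0 lower, without the never mutant ones 9 and 3, and without the mutants 60 and 38. The table-total class as a term gave 1 higher and 0 lower, and a pseudocount of 0.25, or no filter, gave 0.

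Shares of small RNA classes in a library were compared between states in 78 exact permutation tests, 13 classes by 6 pairs of states. GRH bins took 3.57 ± 0.526% of the summed RPKM at F20 and 2.59 ± 0.332% in mutants (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). Chromosome X took 9.92 ± 0.486% early after repair against 8.76 ± 0.62% in mutants, and was higher than in mutants at F20 as well, and histone genes 0.471 ± 0.0164% early against 0.372 ± 0.0646% in never mutant libraries, all at that p. Each was higher in 4 of 4 backgrounds, and with adjusted p = 0.557 none passed the correction. Between never mutant and mutant libraries the GRH share went from 3.83 ± 0.637 to 2.59 ± 0.332% (exact permutation p = 0.0571, n = 4 each). It was lower in each background, with differences of −1.51 to −0.659 percentage points. From mutants to F20 the differences were 0.0426 to 1.76. These tests do not use the pairing by background.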

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

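The comparison of the met-2 set-25 F5 and F20 libraries was set down before its result was seen, but the split of table totals that it rests on was noticed in the data, and the weighing was chosen only then.

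The contrast of early repaired with never mutant libraries differed between set-32 and wild type at 86 bins, 66 higher and 20 lower. Intestine and hypodermis markers, led by vit-2, col-19, col-119 and col-140, differed too (camera adjusted p = 0.032 for each with an estimated correlation). A technical source could be the split of table totals, since both never mutant set-32 libraries have high totals and the repaired ones do not. If so, the same bins should move between the met-2 set-25 F5 library, which has a high total, and its F20 library, which has not. Of the 66 higher bins 61 were lower in the F5 library (92.4%, against 52.4% of all bins), and of the 20 lower ones 16 were higher there (80%, against 47.4%). Most of these bins thus moved the same way with the table total in a background without a set-32 mutation, while an effect of set-32 on them remains untested, as no pair of set-32 libraries before and after repair lies on one side of it.

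GRH bins differed between set-32 and wild type in the same contrast as a list, with a camera adjusted p = 0.0002, and adjusted p = 0.52 with an estimated correlation. The share of microRNAs in set-32(ok1457); hrde-1(tm1200) stood apart from the other 3 mutant libraries, at 1.5% against 0.941 to 0.995%. Its gap to the nearest of them was 0.904 of the whole range, above the 95% limit of Dixon's test. This was 1 of 80 groups of 4 libraries tested, among which chance alone would give 4.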

How the results depend on the processing

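Chosen after seeing the data were the table-total class as a term, the comparison within repaired libraries with its alternatives, the exclusion of misanotated bins, and the pairs of 1 prefix for repaired against mutant libraries; the other alternatives were planned. No value changed its direction past a threshold. Of the counts and values compared, 226 kept and 149 moved. Counts kept if they lay within 1.5 times of the main one, and medians if within a bound taken from the middle 95% of random sets. Comparisons without a call in the main fit that stayed so are among those that kept. Named bins of the mutant against never mutant comparison stayed called in 224 of their alternatives and fell below the threshold in 92. For early against mutant these counts were 65 and 70, for F20 against mutant 85 and 100, for met-2 set-25 167 and 147, for the interaction 146 and 72 while for repaired set-32 63 fell below it. Except where stated, the cause was not tested. Depth limits low bins most, as 3 reads were worth 4.35 to 18.9 RPKM.

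The pseudocount weighs most in bins that lie near 0 in 1 group. A pseudocount of 0.25 gave 37 higher and 78 lower bins for mutant against never mutant, 0 lower for early against mutant, 0 and 0 for F20 against mutant, 0 and 0 for met-2 set-25, 31 and 11 for the interaction and 21 and 12 for repaired set-32. It left 0 or 1 bin to follow in set-32(ok1457), set-32(red11) and met-2 set-25, so no median was had there. A pseudocount of 5 gave 40 lower bins for early against mutant, 3 higher and 51 lower for F20 against mutant, 1 higher for early against never mutant, 9 and 4 for set-32, 127 and 107 for met-2 set-25, 162 and 65 for the interaction and 90 lower for repaired set-32. The medians at hrde-1-dependent lower bins were then −1.16 in the wild-type mutant and −1.43, −2.55 and −2.35 in set-32(ok1457).

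A filter at 1 RPKM, which adds bins of few reads, gave 54 higher and 87 lower for mutant against never mutant, 1 lower for early against mutant, 0 and 13 for F20 against mutant, 19 and 10 for met-2 set-25, and 0 and 0 for the interaction and for repaired set-32. A filter at 20 RPKM gave 3 lower for early against mutant, 0 and 20 for F20 against mutant, 15 and 2 for set-32, 112 and 129 for the interaction and 53 lower for repaired set-32. With no filter 0 bins were called for mutant against never mutant, early or F20 against mutant, met-2 set-25 and repaired set-32. Without that filter the counts were 2943 for set-32 interaction, early repaired, bins higher, 1805 for set-32 interaction, early repaired, bins lower, 2505 for set-32 interaction, hrde-1 mutant, bins higher and 2044 for set-32 interaction, hrde-1 mutant, bins lower.

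Centring on library medians gave 1 lower for early against mutant, 0 and 15 for F20 against mutant, 82 lower for met-2 set-25, 130 higher for the interaction and 71 and 53 for repaired set-32, and medians at dependent bins of −2.07, −0.35 and −0.24 in wild type and of −2.65 early and −2.22 at F20 in set-32(ok1457). For mutant against never mutant, 287 of the 289 bins remained called. Rescaling without microRNA, rRNA and tRNA bins gave 1 lower for early against mutant, 0 and 9 for F20 against mutant and 21 and 23 for met-2 set-25. Requiring 4-fold bins moved the wild-type mutant median to −1.94. Bins called from all 4 backgrounds gave medians of −2.29, −0.19 and −0.17 in wild type, −2.61 early and −2.33 at F20 in set-32(ok1457), and −2.19 in the met-2 set-25 mutant.

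Without the block there were 48 higher and 33 lower bins for mutant against never mutant, 2 higher for early and 1 higher for F20 against never mutant, 16 higher for set-32 and 21 and 20 for met-2 set-25. One additive fit of all 16 libraries gave 90 lower for mutant against never mutant, 11 and 45 for early against mutant, 16 higher for F20 against mutant, 2 higher for early and for F20 against never mutant, and 71 higher and a rounded 1.1e02 lower (184 in all) for met-2 set-25. With the table-total class as a term there were 16 and 76 for early against mutant, 6 and 11 for F20 against mutant, 1 higher for early against never mutant, 58 and 46 for set-32 and 1 and 0 for met-2 set-25. It kept 11 of the 11 early bins and 3 of the 34 F20 bins. Pairs of 1 prefix gave 63 and 61 for early against mutant, 198 and 278 for F20 against mutant, 271 and 381.0 for early against never mutant and 198 and 212 for F20 against never mutant, from set-32 pairs that also cross the split of table totals. They kept all 11 early and all 34 F20 bins. In the comparison set-32 against wild-type background, repaired libraries, bins lower numbered 815 with ok1457 alone (456 higher) and 117 with red11 alone. Without misanotated bins limma called 105 higher and 168 lower for mutant against never mutant.

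Leaving out each background in turn gave 0 to 107 higher and 0 to 163 lower bins for mutant against never mutant, with 0 without set-32(red11). It gave 0 to 2 and 0 to 15 for early against mutant and 0 to 3 and 0 to 47 for F20 against mutant, with 0 without set-32(red11) in both and 0 without met-2 set-25 at F20. Leaving out each state gave 0 to 12 and 0 to 2 for set-32 and 0 to 60 and 0 to 38 for met-2 set-25, with 0 without the F20 libraries. Either allele left out together with the spread taken from an additive fit, changes not made separately, gave 0 and 0 for the interaction. Of the 190 list tests of the 10 planned comparisons 102 passed at the preset correlation and 2 with an estimated one, the intestine and hypodermis markers of the interaction, and of the 19 of repaired set-32 6 and 0.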

Other observations

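The tests in this part were chosen after the result was seen. Reads over all bins of a library were also counted, and 2 of the 4 repaired set-32 libraries held more reads than the wild-type library compared.

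Bins lower in repaired set-32 than in repaired wild-type libraries were in part those that lost small RNAs without hrde-1. Of the 30 bins lower in repaired set-32 libraries 13 were among the 181 lower in hrde-1 mutants, where independent lists would share 0.214, and the lists have no library in common. They lie over F15D4.5, F15D4.6, B0001.5, Y48G1BM.6, T05E8.1, F59A1.9, Y73B3A.9, 3 bins of fbxa-192 and 3 bins of F07B7.1, so that neighbouring or repeated copies count several times. Of the 42 higher bins 6 were among the 108 higher in mutants (0.179 if independent), over kel-1, W05F2.7, F41G4.5, Y61A9LA.7 (2 bins) and an unnamed bin. Y61A9LA.7 (V:4558001–4559000) stood at 1.89 RPKM in N2, 92.9 in the mutant and 2.75 at F20. In set-32(ok1457) it stood at 6.57, 139 and 91.2, and in set-32(red11) at 2.80, 212 and 66.6. In the opposite directions 2 bins of pdfr-1 were higher in mutants and lower in repaired set-32 (0.128 if independent), and 0 were lower and then higher (0.299).

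Single loci did not all follow their background, with genes chosen after their values were seen. fbxa-192 (V:17646001–17647000) stayed low after repair in met-2 set-25 as well, at 110 RPKM before, 18.4 in the mutant, 6.3 at F5 and 0.84 at F20, where wild type had 187, 112, 174 and 158. B0001.5 had 10.2 RPKM in N2 and 166 and 159 in the wild-type repaired libraries, so its repaired level in wild type was not a return to the N2 value. C38D9.2 held a bin (V:17568001–17569000) with more small RNAs after repair than before, at 240 and 247 RPKM in ok1457 against 16.1, 279 and 216 in red11 against 15.6, and 134 and 110 in met-2 set-25 against 27.1, while wild type had 29.1 and 36.3 against 47.1. R03D7.2 (II:10934001–10935000) was at 291 and 351 RPKM in the set-32; hrde-1 mutants and at 10.2 and 11.8 at F20, and in met-2 set-25 it lay between 88.2 and 178 at every state.

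The 5 libraries with high table totals had little signal over the intestine, muscle and hypodermis markers. Lower depth is argued against, since 3 of the 5 held more reads than the median of the others (325 in units of 1000). So is the library-name prefix on its own, since 7 libraries of that prefix had lower totals. Younger animals as the only cause are argued against too, since muscle genes, used at every stage, differed 10.2 times between the medians. Fewer mRNA fragments would lower muscle genes as well, so younger animals together with such a loss cannot be told apart. All 5 carry the prefix SG0717, and preparation batches within a prefix were not tested. Fewer mRNA fragments in these libraries may be a cause, but ribosomal protein genes differed only 1.6 times, between the bounds set for and against it, so it cannot be told apart. Neither set-32 nor met-2 set-25 as a whole coincides with the 5, as libraries of each lie on both sides. Within set-32, however, the split coincides with repair. Totals there were 92.0 to 96.7% in never mutant and mutant libraries and 67.7 to 77.9% in repaired ones, so the split and repair cannot be told apart.

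The bins lower in hrde-1 mutants were lower in repaired set-32 libraries than in repaired wild type. The split of table totals is argued against, since all 4 repaired set-32 libraries, on the same side as wild type, lay below all 10000 random sets. Fewer reads in the set-32 libraries are argued against as well: reads move bins of like mean RPKM alike, whereas in 4 of the 4 the lower bins lay below and the higher bins above all random sets. A standing strain difference cannot be told apart in either allele: never mutant libraries lay −0.04 (ok1457) and −0.46 (red11) from N2 relative to random sets, against mean shifts of −1.57 and −0.95 after repair, but they lie across the split of table totals from N2 and were among the libraries the bins were called from. An effect of set-32 itself, which the design names, stays open and untested, with 1 library per allele and generation. met-2 set-25 was lower at the lower bins (−0.55 and −0.49) and, unlike set-32, at the higher bins too (−0.92 and −0.87). The first value of each pair is from its early library, which lies across the split of table totals from wild type.

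Other splits of the same libraries were refitted. The fits block on background or state, and 8 splits that exchange libraries only within these pairs are too few for a share under 0.05. In such splits mutant against never mutant gave 289 bins in the real split and 0 in the highest other, early against mutant 11 and 0, F20 against mutant 34 and 1, and met-2 set-25 against wild type 73 and 0. The 3 remaining pairs of states gave 0 in all 8. For set-32 against wild type the highest of the 81 splits within states gave 111; its real split, like those 3, gave 0, which any split equals, so nothing follows about chance. Over splits that ignore the block, 35 for each pair and 100 for set-32, the highest others were 0, 12, 125, 2 and 407 in the same order, and 0, 7 and 244 for F20 against early, early against never mutant and F20 against never mutant. In each comparison of pairs 3 of these 35 could not be fitted. The highest of them point to a structure of the samples: that of 407 put all 4 of the high-total libraries on one side, and that of 244 put N2, both never mutant set-32 libraries and the wild-type F20 library together.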
